A study of Homo sapiens with 16 samples.

How the data were processed

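RNA was measured in 16 samples on one-colour Affymetrix arrays, labelled with biotin by the manufacturer's standard protocol per the labels. The deposited table holds 1 value for each of 32321 probe sets and each sample. The values are taken as log2 signals deposited by the authors, because they lie between 3.68 and 14.6 with medians of 7.02 to 7.15 per array. The base of the logarithm, the background correction, the normalization between arrays and the summary of probes are not stated in the sources used here. The values were used as deposited.

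A probe set was kept when the platform's annotation names a single gene (19158 probe sets). Those that name several genes (1388) or are not in the annotation (11775) were left out. For 19128 of the kept ones the gene identifier was found in a separate gene table, with 0 symbols that differ. Of the genes, 637 had more than 1 probe set, and the one with the highest mean over the 16 arrays was taken, which left 18404 genes. No filter on dim genes was applied. The median SD between arrays of a group was 0.152 in resistant, 0.108 in sensitive and 0.133 in brivanib tumours, 0.0819 in parental and 0.0861 in resistant spheres.

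Groups follow the labels. The tumours were compared in a limma fit of the 10 tumour arrays, the spheres in a fit of the 6 sphere arrays, and spheres with tumours, and the difference between the resistance contrasts, in a fit of all 16 arrays, with 1 mean per group and no covariates. Moderated tests (lmFit and eBayes, limma 3.58.1 in R 4.3.3) were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. All adjusted p-values come from limma, and errors beside differences are its standard errors. Before the data were examined, 47 gene lists were written (902 genes, 825 of them measured), including markers of other cell types, along with the comparisons and most alternatives. Lists were tested with limma's camera at a preset correlation between genes of 0.01, two-sided and adjusted over the lists of a comparison. The same lists were tested with an estimated correlation and with fry. Genes named in the text are the 10 with the largest difference in each direction among those past the threshold whose groups do not overlap, a fixed set of growth factor, stem cell and liver genes, and up to 4 members of each called list with the smallest p. Where none passed, the 5 with the smallest p in each direction were taken. A selection of these is printed. Relations between contrasts were tested by permutation of the sample labels.

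Alternatives were quantile normalization, centring arrays on their medians, an intensity trend with robust eBayes, leaving out the 40% dimmest genes, the mean of a gene's probe sets, fits of other sets of arrays, array quality weights, a minimum of 2-fold, a block for the numbers that sphere labels share, and leaving out each array in turn. Leaving out the arrays that correlate least with their own group, and each array in turn for the difference between the contrasts, was chosen after seeing the data. The fits were tested on simulated data of 18404 genes, with normal noise of each gene's own spread. In each comparison known changes were planted in 67 genes at a log2 change of 0.5, 67 at 1 and 66 at 2. For log2 changes of 0.5, 1 and 2 the share recovered was 49.3, 83.6 and 97.0% between resistant and sensitive tumours, 43.3, 86.6 and 100% between brivanib and resistant tumours, 50.7, 92.5 and 100% between the spheres, and 55.2, 91.0 and 100% between spheres and tumours, with 0 in the wrong direction and, in the same order, 10, 19, 11 and 7 unchanged genes called. Camera called 5 of 5 shifted and 0 of 32 unchanged lists in each. With an estimated correlation it called 5 of 5, or 4 of 5 between the spheres, and 0 of 32. Fry called 5 of 5 and 0 of 32, apart from 2 of 32 between resistant and sensitive tumours. The simulated noise was independent between genes, so these list counts do not measure false calls where genes of a list vary together. The recovered shares hold for that noise and those planted changes, and can differ from the power in the real comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. IGF2 has no single-gene probe set and was not analysed here.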

Results

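Expression was measured on 16 one-colour Affymetrix arrays of human sequence, 10 of tumours and 6 of spheres. The tumours grew under the skin of mice from Huh7 cells, a human hepatocellular carcinoma line. Sorafenib, a multikinase inhibitor, was given to 4 tumours that acquired resistance and to 3 that remained responsive, called sensitive here, and 3 further tumours received brivanib, an inhibitor of VEGF and FGF receptors, after resistance had developed. Spheres were grown in suspension, without serum and with added EGF, bFGF and insulin, from the cells of resistant tumours (n = 3) and of untreated tumours (n = 3), the latter called parental here. The series concerns tumour-initiating cells and IGF and FGF signalling in sorafenib resistance, so the comparisons ask what separates resistant from responsive tumours, what brivanib changes after resistance, and what spheres of resistant origin carry. Values for 18404 genes were compared, each as a log2 signal from 1 probe set, and every difference below is on that scale. Median signals per array lay between 7.02 and 7.15. Correlations between arrays of a group ran from 0.983 to 0.990 in resistant, 0.990 to 0.996 in sensitive and 0.987 to 0.992 in brivanib tumours, and from 0.994 to 0.997 in both kinds of sphere. So few arrays limit precision. Limma p reflects the spread of samples, camera p at preset correlation mostly of genes.

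In resistant tumours FREM1, an extracellular matrix protein, rose 1.99-fold over sensitive tumours (8.53 ± 0.10 against 7.54 ± 0.17, SD, n = 4 and 3), a log2 difference of 0.99 ± 0.11 (SE, limma adjusted p = 0.0406). REEP6, which shapes the endoplasmic reticulum, fell by 0.85 ± 0.10 (10.20 ± 0.07 against 11.05 ± 0.12, adjusted p = 0.0406). These were the 2 genes past the threshold, and no array of one group crossed into the other for either. Broader shifts were found in gene lists. Ribosome biogenesis and MYC target genes and cell cycle genes lay higher in resistant tumours, while plasma protein genes of the hepatocyte, interferon response genes and markers of fibroblasts lay lower. The adjusted p of the 10 lists called by camera ran from 0.111 to 0.635 with an estimated correlation.

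Of the 18 measured ribosome biogenesis and MYC target genes, 17 had positive differences, with a mean of 0.34 (camera adjusted p = 2.49e-08, adjusted p = 0.570 with an estimated correlation). Adjusted over the list alone 8 were higher, against 0 over all genes. Nucleolin (NCL) differed by 0.32 ± 0.09 (SE), the box C/D protein NOP58 by 0.49 ± 0.14 and the RNA polymerase I subunit POLR1B by 0.48 ± 0.14, with adjusted p from 0.165 to 0.171. Cell cycle genes averaged 0.23 over 34 members (camera adjusted p = 1.76e-07, adjusted p = 0.570 with an estimated correlation), 1 of them higher adjusted over the list alone and 0 over all genes. The replication licensing factor CDC6 differed by 0.92 ± 0.27, the kinesin KIF11 by 0.57 ± 0.16, topoisomerase TOP2A by 0.42 ± 0.10 and MKI67 by 0.53 ± 0.16, none past the threshold. MAPK pathway output genes averaged 0.16 over 19 members (camera adjusted p = 0.0472, adjusted p = 0.635 with an estimated correlation), with 0 past the threshold over the list alone or over all genes. Among them the ERK phosphatase DUSP6 differed by 0.85 ± 0.23 (adjusted p = 0.147) and DUSP5 by 0.60 ± 0.22 (0.252). NRF2 targets, genes of the oxidative stress response, averaged 0.34 over 21 members (camera adjusted p = 0.000908, adjusted p = 0.622 with an estimated correlation), and 0 passed in either count. The cystine transporter SLC7A11 differed by 0.81 ± 0.21 and GCLC, of glutathione synthesis, by 0.84 ± 0.28. Scores of the NRF2 list overlapped between the groups, from -0.72 to 0.40 in resistant and from -0.97 to -0.23 in sensitive tumours, and without sensitive replicate 2 the mean was 0.099 and not called (adjusted p = 0.108). It was 0.16 without resistant replicate 3 and 0.53 without replicate 4, both called, and the ribosome biogenesis mean was 0.23 without sensitive replicate 2. The MAPK call was lost without resistant replicate 1 (adjusted p = 0.142) or 2 (0.135) or sensitive replicate 1 (0.0691) or 2 (0.0695).

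Plasma proteins made by hepatocytes averaged -0.38 over 28 members (camera adjusted p = 1.76e-07, adjusted p = 0.416 with an estimated correlation), with 12 lower adjusted over the list alone and 0 over all genes. Hemopexin (HPX) went from 10.07 ± 0.39 in sensitive to 8.73 ± 0.25 in resistant tumours, a difference of -1.34 ± 0.20, and fetuin-A (AHSG) differed by -0.69 ± 0.12, both at an adjusted p of 0.0562. Vitronectin (VTN) differed by -0.86 ± 0.17 and FETUB by -0.64 ± 0.12. Interferon response genes averaged -0.23 over 27 members (camera adjusted p = 0.000414, adjusted p = 0.111 with an estimated correlation), 9 of them lower adjusted over the list alone and 0 over all genes. IFITM3 differed by -0.81 ± 0.23, OAS1 by -0.64 ± 0.18 and MX1 by -0.43 ± 0.13 (-0.27 without sensitive replicate 2). Notch pathway genes averaged -0.21 (15 members, camera adjusted p = 0.00967, adjusted p = 0.570 with an estimated correlation), with the ligand DLL4 at -0.91 ± 0.15 and the target HEY1 at -0.69 ± 0.15, and 2 members were lower adjusted over the list alone and 0 over all genes. NF-kB response genes averaged -0.22 (17 members, camera adjusted p = 0.0233, adjusted p = 0.570 with an estimated correlation), with TNFAIP3 at -0.95 ± 0.25 and NFKBIA at -0.65 ± 0.18, and 2 members lower over the list alone and 0 over all genes. Epithelial genes averaged -0.19 (19 members, camera adjusted p = 0.0285, adjusted p = 0.586 with an estimated correlation). Over that list alone 6 were lower and 1 higher, against 0 over all genes, E-cadherin (CDH1) differing by -0.44 ± 0.13 and the tight junction protein TJP1 by 0.43 ± 0.11. Markers of fibroblasts and matrix, which host tissue around a tumour holds, moved with these lower groups and averaged -0.27 (22 members, camera adjusted p = 0.00620, adjusted p = 0.590 with an estimated correlation). Over the list alone 3 of them were lower, against 0 over all genes, with SPARC at -1.39 ± 0.30 and COL5A2 at -0.57 ± 0.13. The host was mouse and the arrays are of human sequence, so markers of other cell types may be read from the tumour cells. Fibroblast scores ran from -0.11 to 0.023 in the spheres and from -0.24 to 0.0029 in resistant tumours, so the list is not a clear measure of host tissue. Vimentin (VIM), measured at 10.18 ± 0.22 against 11.16 ± 0.19, differed by -0.98 ± 0.16 (adjusted p = 0.0562). The epithelial call was lost without resistant replicate 2 (adjusted p = 0.0533) or 4 (0.146) or sensitive replicate 2 (0.108), the fibroblast call without resistant replicate 2 (0.0533), and the NF-kB call without resistant replicate 4 (0.0534) or sensitive replicate 1 (0.0620).

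**Figure D1:**
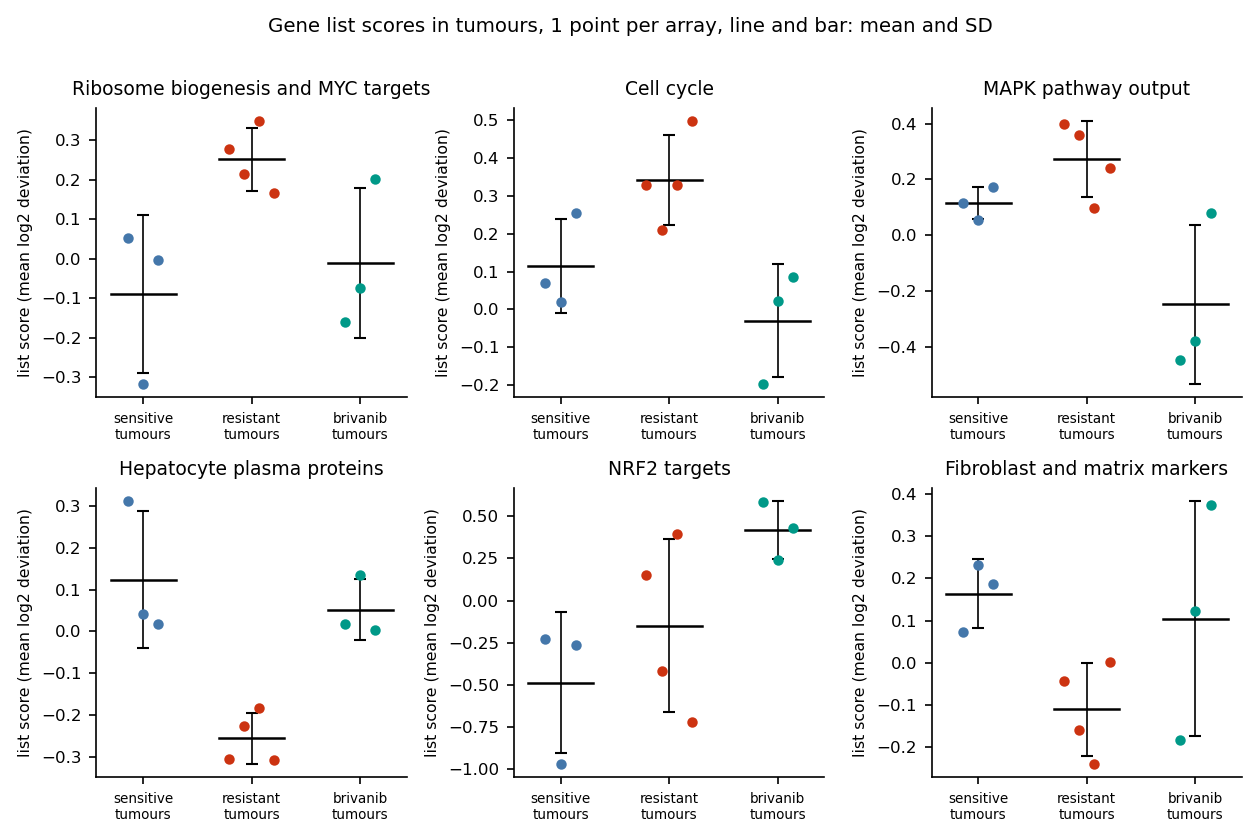
Scores of 6 gene lists in the tumours (vertical axis, mean log2 deviation of the list's members from their mean over all 16 arrays), 1 point per array, with the group mean as a line and the SD as a bar, for 3 sensitive, 4 resistant and 3 brivanib tumours on the horizontal axis. Resistant tumours scored from -0.31 to -0.18 for plasma proteins, below each sensitive (0.02 to 0.31) and brivanib (0.00 to 0.14) tumour.

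After quantile normalization 1 gene was higher and 12 lower, and after centring arrays on their medians 1 and 16. Without an adjustment 2579 genes had a limma p below 0.05 in this comparison, where 920.2 would be expected by chance. The groups did not overlap for 12.8% of all genes, against 5.71% by chance for 4 arrays against 3. The call of both genes was lost on leaving out resistant replicate 1, 3 or 4 or sensitive replicate 1 or 2, and 196 genes were called without resistant replicate 2. Of the 10 lists called by camera 0 were called with an estimated correlation, and among the other splits of the same 7 arrays the median number of lists called was 7.

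After the switch to brivanib, genes of the MAPK pathway's own feedback and of the cell cycle lay lower and genes of hepatocyte function lay higher than in resistant tumours. The resistant tumours were under sorafenib, so the start of brivanib and any end of sorafenib cannot be told apart. With an estimated correlation the adjusted p of the 16 called lists ran from 0.559 to 0.620. DUSP6 went from 11.30 ± 0.12 (SD, n = 4) in resistant tumours to 9.76 ± 0.49 (n = 3), a difference of -1.54 ± 0.23 (SE, limma adjusted p = 0.0170). CDC6 fell from 9.88 ± 0.37 to 8.38 ± 0.56 (adjusted p = 0.0226). The bile salt export pump ABCB11 rose from 6.46 ± 0.94 to 8.46 ± 0.42 (0.0380) and HPX by 0.82 ± 0.20 (0.0443). In all, 933 genes passed the threshold, 310 higher and 623 lower, 117 of them at least 2-fold. With each array centred on its median the split was 232 higher and 863 lower.

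Among the 10 largest rises were PLAAT2, a phospholipase and acyltransferase (2.27 ± 0.53, adjusted p = 0.0417), and CYP1A1, a monooxygenase that acts on foreign compounds (2.06 ± 0.44, 0.0349). PLAAT2 reached 8.34 ± 1.53 with brivanib and CYP1A1 8.49 ± 1.18, the widest spreads among these genes. The lectin MBL2 rose by 1.75 ± 0.32, PALMD by 1.54 ± 0.21, the stress-induced NUPR1 by 1.43 ± 0.17, the ephrin EFNA1 by 1.42 ± 0.19 and CD5, known as a lymphocyte surface protein, by 1.77 ± 0.36. The glutathione transferases GSTA1 (2.16) and GSTA2 (1.52) rose too, but their sequences are nearly identical and the probe sets may not separate them. Among the largest falls were the tetraspanin TSPAN12 (-2.03 ± 0.32, 0.0170), the collagen receptor ITGA2 (-2.02 ± 0.22, 0.00860), the proteoglycan versican VCAN (-1.97 ± 0.24, 0.0105) and the growth factor FGF18 (-1.84 ± 0.28, 0.0170). FAM111B fell by 1.65, ZNF594 by 1.64, CDCA7L by 1.61, and the chemokine receptor CCR6 from 9.18 ± 0.47 to 7.68 ± 0.48.

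MAPK pathway output genes averaged -0.52 over 19 members (camera adjusted p = 0.000239, adjusted p = 0.559 with an estimated correlation). Of these 4 fell over all genes and 12 adjusted over the list alone, where 1 rose. The Sprouty feedback inhibitors SPRY4 (-1.67 ± 0.38, adjusted p = 0.0401), SPRY2 (-1.15 ± 0.19, 0.0190) and SPRY1 (-0.68 ± 0.15, 0.0377) fell with DUSP6. SPRY4 stood at 8.50 in brivanib replicate 3, against 6.87 and 7.04 in replicates 1 and 2. Cell cycle genes averaged -0.37 over 34 members (camera adjusted p = 1.57e-08, adjusted p = 0.559 with an estimated correlation), with 8 lower over all genes and 13 adjusted over the list alone. KIF11 fell by 0.78, the checkpoint kinase BUB1 by 0.56 and TOP2A by 0.44. Ribosome biogenesis and MYC target genes averaged -0.26 (18 members, camera adjusted p = 0.000831, adjusted p = 0.559 with an estimated correlation). POLR1B fell by 0.58 as the 1 member past the threshold in either count, and MYC differed by -0.70 ± 0.23 (adjusted p = 0.0992), or -0.43 without brivanib replicate 2. Replication-dependent histones averaged -0.35 (14 members, camera adjusted p = 0.00152, adjusted p = 0.604 with an estimated correlation), 0 of them called in either count, with H2BC8 at -0.51 ± 0.16 and probe sets that near-identical histone copies may share. Heat shock proteins averaged -0.34 (12 members, camera adjusted p = 0.00304, adjusted p = 0.559 with an estimated correlation), and 2 fell over all genes and 4 over the list alone, among them HSPH1 by 1.34 and DNAJA1 by 0.65. Genes of the unfolded protein response averaged -0.14 (19 members, camera adjusted p = 0.00360, adjusted p = 0.559 with an estimated correlation), of which DNAJB11 alone fell, by 0.39, in both counts, the list's mean being -0.086 without brivanib replicate 3.

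Hepatocyte plasma protein genes averaged 0.31 over 28 members (camera adjusted p = 0.00445, adjusted p = 0.559 with an estimated correlation), 5 higher over all genes and 11 over the list alone. Apolipoprotein APOC3 rose by 0.87 ± 0.20, ITIH3 by 0.71 ± 0.16 and the fibrinogen chain FGA by 0.64 ± 0.11. Genes of bile acid synthesis and transport averaged 0.48 (13 members, camera adjusted p = 0.0113, adjusted p = 0.559 with an estimated correlation), with 4 higher over all genes and 7 over the list alone. Beside ABCB11 these were CYP27A1 (0.96 ± 0.14), the bile acid importer SLC10A1 (0.86 ± 0.13) and CYP8B1 (0.61 ± 0.14). In the urea cycle and amino acid breakdown list the mean was 0.38 (16 members, camera adjusted p = 0.00152, adjusted p = 0.559 with an estimated correlation). HPD rose by 1.22, MAT1A by 0.59 and AGXT by 0.61, the 3 members past the threshold over all genes, against 7 higher and 1 lower over the list alone. Metallothioneins averaged 0.50 (8 members, camera adjusted p = 0.000370, adjusted p = 0.559 with an estimated correlation), 2 higher over all genes, MT1F (0.76) and MT1E (0.50), and 7 over the list alone, in a family whose copies are nearly identical. NRF2 targets averaged 0.57 (21 members, camera adjusted p = 0.0105, adjusted p = 0.620 with an estimated correlation). OSGIN1, a growth inhibitor induced by oxidative stress, rose by 0.94 ± 0.21 as the 1 member past the threshold in either count. Heme oxygenase HMOX1 differed by 1.15 ± 0.36 (adjusted p = 0.0863). NFE2L2, the gene that encodes NRF2 and is not in the list, was lower and past the limma threshold. Acute phase proteins averaged 0.64 (13 members, camera adjusted p = 0.0105, adjusted p = 0.559 with an estimated correlation), with 0 called over all genes and 4 over the list alone, haptoglobin (HP) at 1.54 ± 0.48 and SERPINA3 at 1.33 ± 0.42. Drug metabolism and transport genes averaged 0.47 (18 members, camera adjusted p = 0.0471, adjusted p = 0.559 with an estimated correlation). CYP1A1 was the 1 called member over all genes, with 6 higher and 1 lower over the list alone. For p53 targets the mean was 0.29 (19 members, camera adjusted p = 0.0204, adjusted p = 0.608 with an estimated correlation), with 0 called in either count and CDKN1A at 0.82 ± 0.25 (0.43 without brivanib replicate 1). That replicate scored 0.60 for this list and replicates 2 and 3 scored 0.021 and -0.091, and without replicate 1 the mean was 0.075 and not called (adjusted p = 0.508). Markers of other cells lay higher together with these groups. Fibroblast and matrix markers averaged 0.21 (22 members, camera adjusted p = 0.0212, adjusted p = 0.608 with an estimated correlation), of which COL5A2 (0.68 ± 0.13) and MMP11 (0.59 ± 0.11) rose in both counts, and their scores ran from -0.18 to 0.37 in the 3 brivanib tumours. Without brivanib replicate 3 the mean was 0.080 and not called (adjusted p = 0.213). Erythroid markers averaged 0.19 (7 members, camera adjusted p = 0.0481, adjusted p = 0.559 with an estimated correlation), 0 of them called in either count, with beta-globin HBB at 0.37 ± 0.12. Macrophage and leukocyte markers averaged 0.25, a shift that missed the threshold (camera adjusted p = 0.0515). The drug metabolism call was lost without resistant replicate 2 (adjusted p = 0.134) or 4 (0.0617) or brivanib replicate 1 (0.05003) or 2 (0.113), and the acute phase call without brivanib replicate 2 (0.05195). For NRF2 targets it was lost without resistant replicate 2 (0.0876) or brivanib replicate 1 (0.0757), and the mean was 0.38 without resistant replicate 4. The p53 call was also lost without resistant replicate 1 (0.0701) or 2 (0.0876). The fibroblast call was also lost without resistant replicate 2 (0.0768) or brivanib replicate 2 (0.0626), and that mean was 0.36 without brivanib replicate 1. The erythroid call was lost without resistant replicate 1 (0.0966) or 2 (0.0969) or brivanib replicate 1 (0.121) or 3 (0.138).

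**Figure D2:**
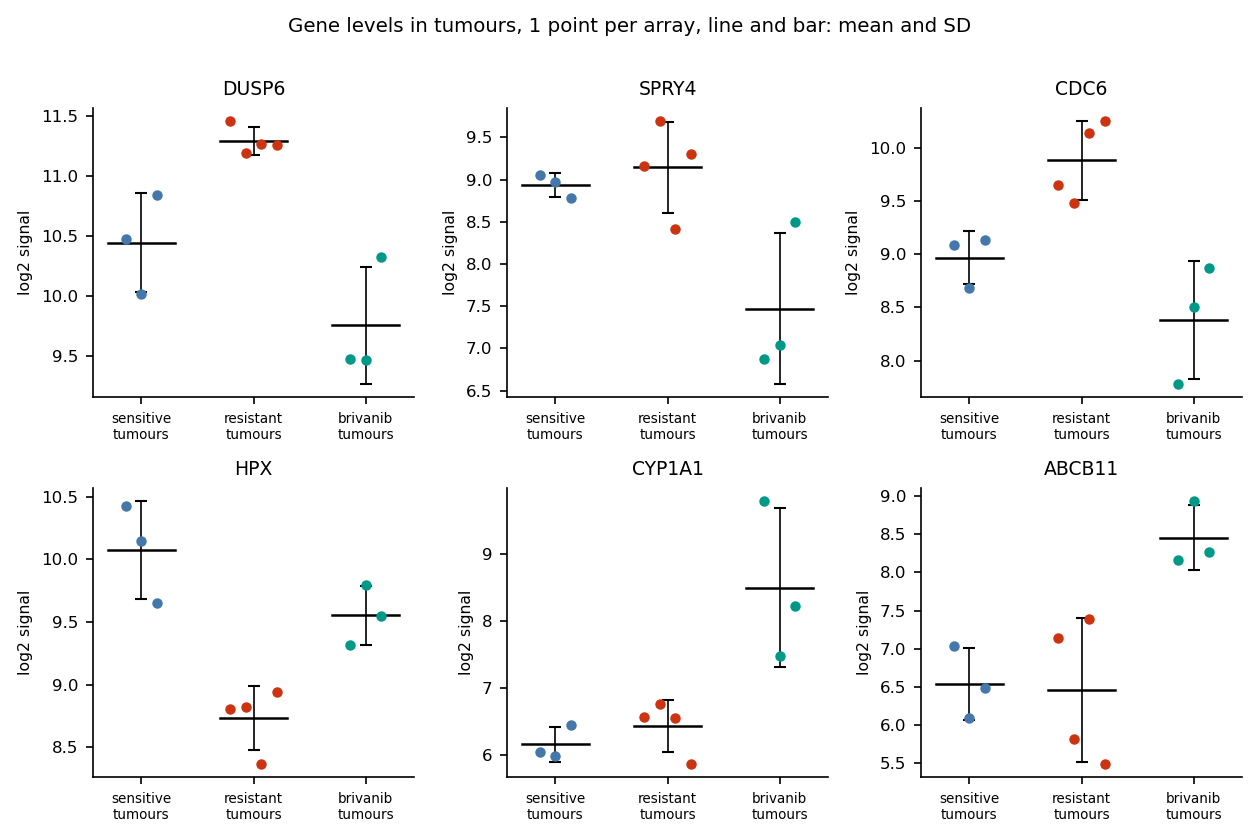
Log2 signal (vertical axis) of 6 genes in each tumour array, by group on the horizontal axis (3 sensitive, 4 resistant and 3 brivanib tumours), with the group mean as a line and the SD as a bar. DUSP6 lay between 11.19 and 11.46 in resistant and between 9.47 and 10.32 in brivanib tumours, and ABCB11 between 5.49 and 7.39 and between 8.16 and 8.94.

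In the limma fit 4557 genes had an unadjusted p below 0.05, and the 2 groups did not overlap for 20.4% of genes, against 5.71% by chance. The count of 933 moved to between 56 (without brivanib replicate 1) and 1862 (without resistant replicate 1) as single arrays were left out. Of the 47 named genes called, 42 lost their call without brivanib replicate 1, 27 and 22 without replicates 2 and 3, 16, 20 and 23 without resistant replicates 2, 3 and 4, and 0 without resistant replicate 1. In a fit of these 7 arrays the 933 fell to 45. TOP2A, BUB1, CYP8B1, DNAJA1, DNAJB11 and POLR1B lost their call after quantile normalization (adjusted p from 0.0516 to 0.0673), and AGXT after centring (0.0561). Of the 16 lists called, 0 were called with an estimated correlation, and other splits of the arrays gave a median of 7 lists.

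Set against sensitive tumours, brivanib tumours had higher NRF2 targets and lower TGF-beta response and MAPK output genes as groups, while 0 single genes passed the limma threshold. The 12 called lists had an adjusted p from 0.702 to 0.761 with an estimated correlation. The sugar-responsive transcription factor MLXIPL stood at 8.12 ± 0.07 against 7.56 ± 0.13 (SD, n = 3 and 3), a difference of 0.56 ± 0.09 (SE, adjusted p = 0.0921), and ITGA2 at 7.09 ± 0.30 against 8.75 ± 0.14, a difference of -1.66 ± 0.23 (adjusted p = 0.0921). The 5 genes of each direction with the smallest p had adjusted p from 0.0921 to 0.101. Those with higher values were MLXIPL, the matrix protein FMOD (0.72), the betaine carrier SLC6A12 (0.88), SP8 (0.62) and CD5 (2.18). Those with lower values were MFAP4 (-0.77), ITGA2, FAM111B (-1.90), the endothelin receptor EDNRB (-1.12) and ARHGAP18 (-1.23). VIM differed by -1.13 ± 0.17 (adjusted p = 0.0921) and the surface marker CD24 by -1.18 ± 0.26 (0.109).

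NRF2 targets averaged 0.91 over 21 members (camera adjusted p = 3.71e-09, adjusted p = 0.702 with an estimated correlation), 8 of them higher adjusted over the list alone and 0 over all genes, with GCLC at 1.38 ± 0.30 and OSGIN1 at 0.99 ± 0.23. TGF-beta response genes averaged -0.35 (14 members, camera adjusted p = 0.00707, adjusted p = 0.702 with an estimated correlation). The pseudoreceptor BAMBI differed by -1.23 ± 0.24 and LTBP1, which binds latent TGF-beta, by -1.16 ± 0.28, and 2 members were lower over the list alone. MAPK output averaged -0.36 (19 members, camera adjusted p = 0.00917, adjusted p = 0.720 with an estimated correlation), with SPRY2 at -1.04 ± 0.20, SPRY4 at -1.46 ± 0.41, and 3 lower and 1 higher over the list alone. Brivanib replicate 3 scored 0.080 for MAPK output, inside the sensitive range of 0.055 to 0.17, against -0.45 and -0.38 in replicates 1 and 2. The MAPK call was lost without brivanib replicate 1 (adjusted p = 0.0568) or 2 (0.0652), and the TGF-beta call without replicate 2 (0.0652). Cholesterol synthesis genes averaged -0.19 (18 members, camera adjusted p = 0.00707, adjusted p = 0.702 with an estimated correlation), 3 lower over the list alone, including FDPS at -0.55 ± 0.12 and CYP51A1 at -0.49 ± 0.15. Metallothioneins averaged 0.33 (camera adjusted p = 0.00707, adjusted p = 0.720 with an estimated correlation), with MT2A at 0.39, and p53 targets averaged 0.29 (camera adjusted p = 0.00707, adjusted p = 0.720 with an estimated correlation), with AEN at 1.08 (0.69 without brivanib replicate 1). Neither list had a member past the threshold over the list alone, and the p53 mean rested on brivanib replicate 1, without which it was 0.083 (adjusted p = 0.196). For replication-dependent histones the mean was -0.34 (camera adjusted p = 0.00707, adjusted p = 0.761 with an estimated correlation), with 1 lower over the list alone and H2BC21 at -1.10, and for heat shock proteins it was -0.25 (camera adjusted p = 0.0151, adjusted p = 0.702 with an estimated correlation), with 1 lower and HSPH1 at -0.79. Urea cycle and amino acid breakdown genes averaged 0.22 (camera adjusted p = 0.0217, adjusted p = 0.702 with an estimated correlation), 3 higher and 1 lower over the list alone, with HPD at 0.82. ATF4 targets averaged 0.23 (camera adjusted p = 0.0288, adjusted p = 0.761 with an estimated correlation), with 0 past the threshold in either count and NUPR1 at 0.73. Cell cycle genes averaged -0.14 (camera adjusted p = 0.0474, adjusted p = 0.761 with an estimated correlation), with 0 past it and MCM3 at -0.47 (-0.27 without brivanib replicate 1). Erythroid markers again lay higher, by 0.19 (camera adjusted p = 0.0335, adjusted p = 0.720 with an estimated correlation), with 0 called over the list alone and HBB at 0.42. Without sensitive replicate 2 the ATF4 mean was 0.10 and not called (adjusted p = 0.476), nor was it called without brivanib replicate 1 (0.0649) or 2 (0.0636). The cell cycle mean was -0.060 without brivanib replicate 1 (0.365) and -0.073 without sensitive replicate 3 (0.543). The histone mean was -0.17 without sensitive replicate 3 (0.170) and -0.59, still called, without replicate 2, and its call was also lost without sensitive replicate 1 (0.0515) or brivanib replicate 1 (0.0636). The cholesterol call was lost without sensitive replicate 1 (0.0526), the heat shock call without sensitive replicate 1 (0.0526) or 3 (0.0836), and the erythroid call without sensitive replicate 1 (0.0526) or 2 (0.0889) or brivanib replicate 1 (0.0636) or 3 (0.159). The urea cycle call was lost without sensitive replicate 3 (0.0809) or brivanib replicate 1 (0.0636) or 2 (0.0652), and the metallothionein mean was 0.20 without brivanib replicate 3 and still called.

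Beside the 0 genes called by limma, 3008 had an unadjusted p below 0.05, and the groups did not overlap for 25.5% of genes, against 10% by chance for 3 arrays against 3. With array quality weights limma called 1297 genes, with these 6 arrays fitted alone 500, and with all 16 arrays in the fit 672. None of the 12 called lists was called by camera with an estimated correlation or by fry.

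Across genes, the differences of brivanib from resistant tumours were set against those of resistant from sensitive tumours. With the resistant arrays divided so that the contrasts shared none, Pearson's r averaged -0.264 over 6 divisions, from -0.652 to 0.0712 depending on which resistant arrays went where, and a permutation of the tumour labels gave a two-sided p of 0.289 from 4200 relabellings. Shared resistant arrays gave r = -0.452 (permutation p = 0.476), where unchanged groups simulated against the same arrays gave -0.427. The covariance was -0.0322 against a simulated -0.0107, a difference of -0.0215. Genes are not independent replicates, and the relation did not stand apart from relabelled arrays.

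Spheres from resistant tumours had higher cholesterol synthesis, cell cycle, NRF2 and oncofetal liver genes than spheres from untreated tumours, and lower ATF4 and YAP targets. Adjusted p with an estimated correlation ran from 0.321 to 0.545 over the 19 called lists. TXNIP, the thioredoxin-interacting protein, rose 8.20-fold, from 6.64 ± 0.28 to 9.67 ± 0.79 (SD, n = 3 and 3), a difference of 3.03 ± 0.35 (SE, limma adjusted p = 0.00700). The quinone reductase NQO1 rose by 2.14 ± 0.27 (0.00871), and mevalonate kinase MVK by 0.88 ± 0.09 (0.00531). VCAN fell by 2.23 ± 0.21 (0.00519) and the YAP target CCN1 by 1.11 ± 0.09 (0.00381). The threshold was passed by 1134 genes, 655 higher and 479 lower, 90 of them at least 2-fold.

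The 10 largest rises included, after TXNIP, the fetal gene DLK1 (2.43 ± 0.30), pepsinogen C PGC (2.40 ± 0.39), haptoglobin HP (2.17 ± 0.43), MYLK4 (2.13 ± 0.41), the estrogen sulfotransferase SULT1E1 (2.11 ± 0.18), FGL1 (2.11 ± 0.49), the deiodinase DIO1 (2.05 ± 0.31) and ABCB11 (1.84 ± 0.18). FGL1 lost its call after quantile normalization or centring on medians (adjusted p = 0.0538 and 0.0514), as did GTSF1 after centring. Beside VCAN the largest falls were in the matrix proteins reelin RELN (-2.42 ± 0.50) and thrombospondin THBS1 (-1.62 ± 0.24), in ANKRD1 (-1.68 ± 0.19), the calcium sensor SCGN (-1.71 ± 0.29), the metalloprotease TLL1 (-1.59 ± 0.21), the channel KCNH7 (-1.57 ± 0.32), RASEF (-1.48 ± 0.15), GTSF1 (-1.45 ± 0.33) and CD3G, known as a T cell receptor subunit (-1.43 ± 0.25). Their adjusted p ran from 0.00381 to 0.0495.

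Cholesterol synthesis was the list with the smallest p, averaging 0.51 over 18 members (camera adjusted p = 1.37e-12, adjusted p = 0.366 with an estimated correlation). It had 11 members higher over all genes and 16 over the list alone, and 0 lower. MVD rose by 0.79 ± 0.08, IDI1 by 0.66 ± 0.08 and SQLE by 0.63 ± 0.08. Fatty acid synthesis genes averaged 0.32 (17 members, camera adjusted p = 8.28e-05, adjusted p = 0.474 with an estimated correlation). Over all genes 7 rose and 1 fell, over the list alone 8 and 1, with ACSS2 at 1.39 ± 0.14, fatty acid synthase FASN at 0.65 ± 0.11 and ACACA at 0.37 ± 0.06. In the cell cycle list, mean 0.32 over 34 members (camera adjusted p = 5.42e-11, adjusted p = 0.477 with an estimated correlation), 14 rose over all genes and 19 over the list alone. They included the mitotic genes KIF20A (0.89 ± 0.06), AURKA (0.61 ± 0.08), CCNB2 (0.59 ± 0.06) and PLK1 (0.56 ± 0.06). NRF2 targets averaged 0.52 (21 members, camera adjusted p = 3.72e-08, adjusted p = 0.474 with an estimated correlation), 6 rising and 1 falling over all genes and 12 and 1 over the list alone. GPX2 rose by 1.40 ± 0.17 and TKT by 0.61 ± 0.06, while SLC7A11, also an ATF4 target, fell by 0.59 ± 0.10. Oncofetal liver genes averaged 0.67 (10 members, camera adjusted p = 8.47e-06, adjusted p = 0.321 with an estimated correlation), 5 higher over all genes and, over the list alone, 7 higher and 1 lower. Beside DLK1 these were MEST (1.35 ± 0.17), SALL4 (1.09 ± 0.08) and LIN28B (0.44 ± 0.07). The urea cycle and amino acid breakdown list averaged 0.36 (16 members, camera adjusted p = 0.00170, adjusted p = 0.365 with an estimated correlation). Ornithine transcarbamylase OTC rose by 1.52 ± 0.23 and AGXT by 0.77 ± 0.11, 2 of 6 over all genes, with 9 higher and 2 lower over the list alone.

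Plasma protein genes averaged 0.25 (28 members, camera adjusted p = 0.0278, adjusted p = 0.490 with an estimated correlation), 5 higher over all genes and, over the list alone, 8 higher and 1 lower. APOH rose by 1.01 ± 0.14, APOC3 by 0.78 ± 0.12 and RBP4 by 0.46 ± 0.05. Acute phase proteins averaged 0.45 (13 members, camera adjusted p = 0.0289, adjusted p = 0.474 with an estimated correlation), with 3 called in both counts, among them HP, FGL1 and ceruloplasmin CP (0.63 ± 0.07). Glycolysis genes averaged 0.23 (17 members, camera adjusted p = 0.00885, adjusted p = 0.490 with an estimated correlation) and hypoxia response genes 0.15 (28 members, camera adjusted p = 0.00885, adjusted p = 0.545 with an estimated correlation). Of the former 3 rose in both counts, including hexokinase HK1 (1.07 ± 0.09) and ALDOC (1.03 ± 0.10). Of the latter 4 rose, among them PFKFB4 (0.61), and 1 fell, ANGPTL4 (-0.66). Oxidative phosphorylation genes averaged 0.08 (41 members, camera adjusted p = 0.0169, adjusted p = 0.533 with an estimated correlation), with 3 higher and 1 lower over all genes and 5 and 1 over the list alone, NDUFA1 rising by 0.35 and NDUFS7 falling by 0.30. Without resistant replicate 3 the mean of that list was 0.039 and not called (adjusted p = 0.304), and without parental replicate 2 the hypoxia mean was 0.10 (0.117) and the glycolysis call lost (0.0677). The plasma protein call was lost without parental replicate 5 (0.100) or resistant replicate 1 (0.165), and so was the acute phase call (0.100 and 0.106).

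ATF4 targets, genes of the amino acid stress response, averaged -0.28 over 27 members (camera adjusted p = 4.91e-08, adjusted p = 0.365 with an estimated correlation), 7 lower over all genes and 16 over the list alone. CHAC1 fell by 0.90 ± 0.09 and SESN2 by 0.79 ± 0.10. YAP and TAZ targets averaged -0.31 (22 members, camera adjusted p = 0.000971, adjusted p = 0.365 with an estimated correlation), with 4 lower over all genes, including NT5E (-0.83 ± 0.08), and 7 over the list alone. TGF-beta response genes averaged -0.25 (14 members, camera adjusted p = 0.0105, adjusted p = 0.365 with an estimated correlation), of which LTBP1 (-1.20 ± 0.16) was the 1 member called in either count. MAPK output averaged -0.14 (19 members, camera adjusted p = 0.00885, adjusted p = 0.490 with an estimated correlation). DUSP4 (-0.62 ± 0.06) and the receptor EPHA2 (-0.50 ± 0.10) fell over all genes, against 4 lower and 1 higher over the list alone. NF-kB response and chemokine genes averaged -0.25 (17 members, camera adjusted p = 0.0110, adjusted p = 0.490 with an estimated correlation), with 5 lower over all genes and, over the list alone, 6 lower and 1 higher. The chemokines CCL20 (-1.21 ± 0.23), CXCL5 (-1.16 ± 0.18) and CXCL8 (-0.84 ± 0.15) fell. Notch pathway genes averaged -0.16 (15 members, camera adjusted p = 0.0278, adjusted p = 0.474 with an estimated correlation), 3 lower over all genes and 4 over the list alone, with the ligand JAG1 at -0.99 ± 0.14 and NOTCH1 at -0.41 ± 0.08. Unfolded protein response genes averaged -0.15 (19 members, camera adjusted p = 0.00885, adjusted p = 0.490 with an estimated correlation), 0 called in either count, with calreticulin CALR at -0.32 ± 0.09. Immediate early genes averaged -0.10 (18 members, camera adjusted p = 0.0499, adjusted p = 0.474 with an estimated correlation), FOS being the 1 member called over all genes (-0.37 ± 0.08), with 4 lower and 1 higher over the list alone. The MAPK mean was -0.073 without resistant replicate 2 (adjusted p = 0.0763) and -0.083 without parental replicate 5 (0.100), neither called. The Notch call was lost without parental replicate 5 (0.116) or resistant replicate 1 (0.0725) or 3 (0.0770), and the immediate early call without parental replicate 1 (0.0936) or 5 (0.188) or resistant replicate 2 (0.0924) or 3 (0.115). No list of other cell types was called in the spheres.

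Before adjustment 4031 genes had a limma p below 0.05, and the groups did not overlap for 27.2% of genes, against 10% by chance. The count of 1134 moved to 199 without resistant replicate 2, 241 without parental replicate 1, 293 without parental replicate 2 and 634 without resistant replicate 3. Of the 66 named genes called, 29, 25 and 6 lost their call without parental replicates 1, 2 and 5, and 3, 27 and 14 without resistant replicates 1, 2 and 3. None of the 19 called lists was called with an estimated correlation, fry called 10 lists of which 7 were among them, and the other splits of these 6 arrays gave a median of 7 lists.

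Grown as spheres, cells of resistant origin had higher amino acid stress, cholesterol, hypoxia and drug metabolism genes than resistant tumours and lower cell cycle genes. For the 14 called lists the adjusted p with an estimated correlation ran from 0.135 to 0.667. The stress factor DDIT3 rose by 1.82 ± 0.13 (SE, 10.79 ± 0.15 against 8.98 ± 0.07, SD, n = 3 and 4, limma adjusted p = 1.51e-06), asparagine synthetase ASNS by 1.26 ± 0.20 and CTH by 1.62 ± 0.20. Cyclin CCNA2 fell by 0.69 ± 0.09 (adjusted p = 8.14e-05). The largest rises were in SPX (3.70), GSTA1 (3.59), CYP1A1 (3.49), the transporter SLCO1B3 (3.40), DIO1 (3.32), GSTA2 (3.27), SNORD60 (2.89), the carboxylesterase CES1 (2.81), the glucose transporter SLC2A3 (2.79) and RANBP3L (2.66, and 1.75 without resistant sphere replicate 1). The largest falls were in cathepsin E CTSE (-3.05), SLC6A14 (-2.82), neurotensin NTS (-2.67), SMPDL3B (-2.62), SQOR (-2.55), BPIFB2 (-2.48), the keratin KRT23 (-2.42), CD38 (-2.38), PCDHB14 (-2.36) and IRAK3 (-2.34). Adjusted p among these 20 genes ran from 2.09e-07 to 0.00656. In total 4047 genes passed, 2167 higher and 1880 lower, and centring arrays on their medians changed that split to 2807 and 1406.

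ATF4 targets averaged 0.69 over 27 members (camera adjusted p = 7.07e-09, adjusted p = 0.315 with an estimated correlation), 16 higher over all genes and 20 over the list alone. Cholesterol synthesis genes averaged 0.59 (18 members, camera adjusted p = 7.07e-09, adjusted p = 0.135 with an estimated correlation), with 14 and 15 higher by the same counts, including SC5D (1.03 ± 0.12), DHCR7 (0.99 ± 0.11) and SREBF2 (0.81 ± 0.11). For hypoxia response genes the mean was 0.47 (28 members, camera adjusted p = 1.01e-06, adjusted p = 0.315 with an estimated correlation). Of these 14 rose over all genes, among them PFKFB4 (1.31), P4HA2 (1.22) and VEGFA (0.71), and 14 rose and 1 fell over the list alone. Drug metabolism genes averaged 0.96 (18 members, camera adjusted p = 0.000320, adjusted p = 0.315 with an estimated correlation), 7 higher over all genes and 10 over the list alone, SULT2A1 rising by 2.63 ± 0.40. Plasma protein genes averaged 0.47 (28 members, camera adjusted p = 9.35e-05, adjusted p = 0.315 with an estimated correlation). Over all genes 12 rose and 2 fell, over the list alone 16 and 2, with APOC3 at 1.91 ± 0.18, ITIH1 at 1.76 ± 0.18 and FGB at 1.12 ± 0.08. Fatty acid synthesis genes averaged 0.37 (camera adjusted p = 0.00600, adjusted p = 0.479 with an estimated correlation), with 8 higher and 1 lower over all genes, 9 and 1 over the list alone, and ACSS2 at 1.77. Fatty acid oxidation genes averaged 0.28 (camera adjusted p = 0.0224, adjusted p = 0.498 with an estimated correlation), with 5 higher and 2 lower over all genes, 6 and 2 over the list alone, and CPT1A at 1.75. Urea cycle and amino acid breakdown genes averaged 0.48 (camera adjusted p = 0.00236, adjusted p = 0.315 with an estimated correlation), 6 higher over all genes, MAT1A among them (7.27 ± 0.14 to 8.78 ± 0.20), and 7 higher and 1 lower over the list alone. Unfolded protein response genes averaged 0.25 (camera adjusted p = 0.00600, adjusted p = 0.504 with an estimated correlation), 7 and 8 higher by the same counts, with HYOU1 at 0.74. NRF2 targets averaged 0.54 (camera adjusted p = 0.00208, adjusted p = 0.667 with an estimated correlation), 4 higher in both counts, OSGIN1 by 0.84. Metallothioneins averaged 0.37 (camera adjusted p = 0.0224, adjusted p = 0.667 with an estimated correlation), 3 and 4 higher, MT1F by 0.67. Cell cycle genes averaged -0.45 over 34 members (camera adjusted p = 6.42e-10, adjusted p = 0.460 with an estimated correlation), with 21 lower over all genes and 27 over the list alone, including BUB1B (-0.75 ± 0.13), KIF11 (-0.83 ± 0.15) and MKI67 (-0.68 ± 0.15). MAPK output averaged -0.46 (camera adjusted p = 0.00227, adjusted p = 0.540 with an estimated correlation), 8 lower and 1 higher over all genes and 10 and 1 over the list alone, with SPRY4 at -1.92 ± 0.35, IER3 at -1.17 ± 0.21 and EGR1 at -0.96 ± 0.19. Ribosome biogenesis and MYC target genes averaged -0.34 (camera adjusted p = 0.000959, adjusted p = 0.570 with an estimated correlation), 8 lower in both counts, DKC1 by -0.77 and NCL by -0.56. CD24 fell by 1.24 ± 0.24. Without resistant sphere replicate 3 the metallothionein mean was 0.23 and not called (adjusted p = 0.124), nor was it called without resistant tumour replicate 2 (0.0850). The fatty acid oxidation call was lost without resistant tumour replicate 1 (0.0787) or 2 (0.107), and the NRF2 mean was 0.35 without resistant tumour replicate 4.

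The unadjusted limma p was below 0.05 for 6150 genes, and the groups did not overlap for 29.8% of genes, against 5.71% by chance. The spheres' medium held EGF, bFGF and insulin, which bears on the MAPK, growth factor and lipid genes compared, and neither it nor a batch of arrays, if tumours and spheres were hybridised apart, can be told apart from the kind of sample. The count was 2610 without resistant sphere replicate 2, and of the 14 lists 0 were called with an estimated correlation.

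The resistance contrasts of tumours and spheres differed for hepatocyte and lipid genes. Plasma protein genes lay lower in resistant tumours and higher in resistant spheres (the latter not called without parental replicate 5, adjusted p = 0.100, or resistant replicate 1, 0.165), while cholesterol and fatty acid synthesis lay higher in spheres and were not called in tumours (-0.12, camera adjusted p = 0.154, and -0.12, 0.2996). None of these lists was called in either contrast with an estimated correlation. Versican differed by 0.81 in tumours (resistant minus sensitive) and by -2.23 in spheres (resistant minus parental), an interaction of 3.04 ± 0.36 (SE, limma adjusted p = 0.00312, all 16 arrays). For TXNIP the values were -0.08 and 3.03, an interaction of -3.11 ± 0.44 (adjusted p = 0.00806). The interaction passed the threshold for 218 genes, 63 higher and 155 lower, 105 of them at least 2-fold. With 1 array left out the count was 60 and 78 without parental spheres 2 and 1, 70 and 129 without resistant spheres 2 and 1, 120 and 121 without sensitive tumours 1 and 2, 347 without resistant tumour 2, and 156 to 301 otherwise. The controls of the contrasts differ, since sensitive tumours had received sorafenib and parental spheres came from untreated tumours. Cholesterol synthesis genes had a mean interaction of -0.62 over 18 members (camera adjusted p = 1.20e-13, adjusted p = 0.0243 with an estimated correlation), the 1 list that stayed past the threshold with an estimated correlation. Over all genes 4 were lower and over the list alone 15, with paired tumour and sphere differences for INSIG1 (-0.21 and 1.03, adjusted p = 0.0159), MVK (-0.12 and 0.88, adjusted p = 0.0290) and EBP (-0.25 and 0.40, adjusted p = 0.0240). Plasma protein genes had a mean interaction of -0.63 (28 members, camera adjusted p = 9.57e-10, adjusted p = 0.110 with an estimated correlation), with 5 lower over all genes and, over the list alone, 14 lower and 1 higher. Among them were APOC3 (-0.93 and 0.78, adjusted p = 0.0105), HPX (-1.34 and 0.40, adjusted p = 0.0271) and AHSG (-0.69 and 0.39, adjusted p = 0.0120). Fatty acid synthesis genes averaged -0.44 (camera adjusted p = 2.45e-05, adjusted p = 0.141 with an estimated correlation), 2 lower over all genes and 4 over the list alone, ACSS2 by -1.65 and PNPLA3 by -1.23. ATF4 targets averaged 0.40 (camera adjusted p = 4.72e-06, adjusted p = 0.258 with an estimated correlation), with SLC7A11 higher by 1.40 over all genes and 8 higher and 1 lower over the list alone. MAPK output averaged 0.30 (camera adjusted p = 0.00162, adjusted p = 0.445 with an estimated correlation), with DUSP4 higher by 0.82, and 1 higher and 1 lower over the list alone. The calls of VCAN, TXNIP, APOC3, AHSG, PNPLA3, DUSP4 and these 5 lists stayed with each array left out. HPX lost its call without sensitive tumour 1 or 2, parental sphere 1 or 5 or resistant sphere 1 or 3 (adjusted p from 0.0559 to 0.0764), and its sphere value was 0.15 without resistant sphere 1, 0.26 without parental sphere 5 and 0.66 without resistant sphere 2. MVK lost its call without sensitive tumour 1 or 3 or any sphere but parental 5 (0.0511 to 0.0942), EBP without sensitive tumour 1 or 3 or any sphere but resistant 3 (0.0521 to 0.0759), and SLC7A11 without sensitive tumour 1 or 2, parental sphere 1 or 2 or resistant sphere 1 (0.0559 to 0.0738). INSIG1 and ACSS2 lost theirs without parental sphere 2 (0.0566 and 0.0575) or resistant sphere 2 (0.0513). Tumour values close to 0 moved as well, for MVK from -0.22 without resistant tumour 1 to 0.032 without 4, for TXNIP from -0.23 without sensitive tumour 1 to 0.00042 without resistant tumour 1, and for INSIG1 to -0.13 without resistant tumour 2 or 4.

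**Figure D3:**
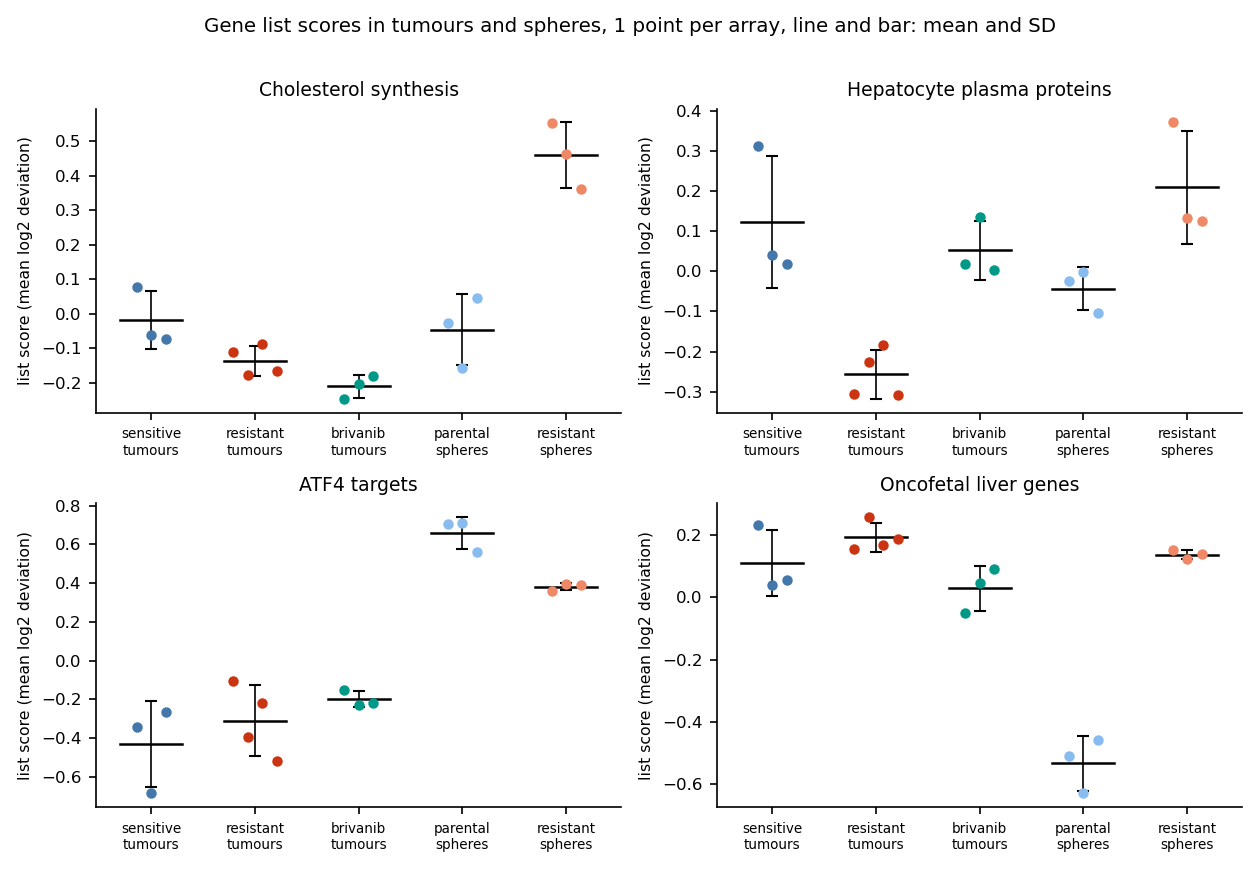
Scores of 4 gene lists (vertical axis, mean log2 deviation of the members from their mean over all 16 arrays) in each array of the 5 groups on the horizontal axis, with the group mean as a line and the SD as a bar. Resistant spheres scored from 0.36 to 0.55 for cholesterol synthesis and every other array at 0.08 or less, and parental spheres scored from -0.63 to -0.46 for oncofetal liver genes.

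Over 18404 genes the differences of the contrasts correlated with Pearson's r = 0.135 (permutation p = 0.371, 700 relabellings) and Spearman's rho = 0.180 (permutation p = 0.177), and 57.7% of genes had the same sign, genes not being independent replicates. Pearson's r was 0.0603 without parental sphere replicate 5 and 0.0788 without resistant tumour replicate 3. FREM1 differed in spheres by 0.49 (adjusted p = 0.505), or by -0.0033 without resistant sphere replicate 1 and 0.78 without replicate 3, and REEP6 by -0.15 (0.258), so that 0 genes were called in both, where independent calls would give 0.0356 higher and 0.0260 lower. Among the lists, 6 were called in both contrasts, 4 in the same direction (cell cycle, NRF2, Notch and NF-kB) and 2 in opposite ones (plasma proteins and MAPK output). With an estimated correlation 0 of these 6 were called in either contrast, the adjusted p running from 0.416 to 0.635 in tumours and from 0.474 to 0.490 in spheres. Of the 6, cell cycle alone was called in both contrasts with each array left out in turn. In tumours the calls of NRF2 (0.108), MAPK output (up to 0.142) and NF-kB (up to 0.0620) were lost without at least 1 array. In spheres the same held for plasma proteins (up to 0.165), MAPK output (up to 0.100) and Notch (up to 0.116).

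Of the growth factor genes named beforehand, FGFR1 stood at 8.04 ± 0.17 in resistant, 7.37 ± 0.15 in sensitive and 7.59 ± 0.13 in brivanib tumours (SD), differences of 0.66 ± 0.11 (SE, adjusted p = 0.0562) and, for brivanib against resistant, -0.44 ± 0.11 (0.0526), neither past the threshold. IGF1R differed by 0.71 ± 0.42 between resistant and sensitive tumours (adjusted p = 0.509), with an SD of 0.94 among resistant tumours, and by 1.14 without resistant replicate 4 and 0.40 without replicate 1, not called in either case. It rose by 0.59 ± 0.07 in resistant over parental spheres (0.00873). In the same spheres IGFBP3 fell by 0.55 (0.0267), FGF2 by 0.54 (0.0282) and CD24 by 1.13 (0.0164). CD24 differed by -0.79 ± 0.25 in resistant tumours (0.188) and VEGFA by -0.35 ± 0.10 (0.174). Resistant spheres had higher FGFR4 (0.35) and its coreceptor KLB (0.66) and lower FGFR1 (-0.36) than resistant tumours, the last call being lost after quantile normalization (adjusted p = 0.0519) or centring (0.0813). The list of FGF ligands, receptors and adaptors (30 measured) averaged 0.01 in resistant against sensitive tumours and -0.01 in spheres, the IGF and insulin list (21) -0.08 and -0.04, and the stem and progenitor list (21) -0.08 and 0.01. None of these was called in any comparison. In all, 14 of the 47 lists were called in none, among them endothelial, adipocyte, muscle, keratinocyte and cholangiocyte markers, angiogenic factors and ribosomal proteins.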

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

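The explanations weighed here and the counts over other splits of the arrays were tests chosen only after the results were seen, while the rules that single out arrays and differences were fixed before.

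In the 4 resistant tumours, 9 of 151 genes and 1 of 32 lists had an array far from the other 3, by a gap over range above Dixon's 95% critical value. Chance gives about 1 in 20 such cases. Replicate 4 stood low for HP (7.67 against 8.98 to 9.06, ratio 0.941), SLC10A1 (6.06 against 6.37 to 6.38, 0.955), SLC6A14 (10.67 against 11.86 to 12.10, 0.835) and the acute phase protein score (-0.60 against 0.07 to 0.14, 0.905). Replicate 2 stood low for MBL2 (7.52 against 8.11 to 8.17, 0.899) and MKI67 (10.58 against 11.18 to 11.24, 0.905) and high for SMPDL3B (10.36 against 9.87 to 9.95, 0.841). Replicate 1 stood high for FGF18 (10.80 against 10.04 to 10.17, 0.830) and HYOU1 (9.74 against 9.34 to 9.40, 0.836), and replicate 3 for FGA (12.44 against 12.19 to 12.22, 0.869).

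The resistance contrasts of tumours and spheres differed by an interaction test for 218 genes. Genes with a higher contrast in tumours were VCAN (3.04), GALNT5 (1.87), TLL1 (1.48), SLC7A11 (1.40), MMP16 (1.31), CCN1 (1.29) and DUSP4 (0.82). Genes with a lower one were TXNIP (-3.11), VCAM1 (-3.02), PGC (-2.69), LEAP2 (-2.59), FXYD3 (-2.54), DIO1 (-2.33), HPX (-1.74), APOC3 (-1.71), AHSG (-1.08), ACSS2 (-1.65), ALDOC (-1.60), MEST (-1.40), INSIG1 (-1.24), PNPLA3 (-1.23), CPT1A (-1.22), AGXT (-1.20), MAT1A (-1.02), MVK (-1.0003), RHBG (-0.91), DHCR7 (-0.80), IFIT1 (-0.75) and EBP (-0.65). Called lists, with the camera adjusted p and the adjusted p with an estimated correlation, were lower in tumours for cholesterol synthesis -0.62 (1.20e-13, 0.0243), plasma proteins -0.63 (9.57e-10, 0.110), acute phase proteins -0.69 (0.0212, 0.467), oncofetal liver genes -0.59 (0.0101, 0.141), urea cycle and amino acid breakdown -0.52 (0.00139, 0.214), fatty acid synthesis -0.44 (2.45e-05, 0.141) and Wnt targets -0.43 (0.00371, 0.141). They were also lower for glycolysis -0.30 (0.0277, 0.442), fatty acid oxidation -0.27 (0.0101, 0.258), hypoxia response -0.27 (9.26e-05, 0.258), macrophage and leukocyte markers -0.20 (0.0348, 0.472), interferon response -0.18 (0.0348, 0.141) and oxidative phosphorylation -0.14 (0.0193, 0.699). They were higher for ATF4 targets 0.40 (4.72e-06, 0.258), MAPK output 0.30 (0.00162, 0.445), ribosome biogenesis and MYC targets 0.27 (0.000859, 0.467), YAP and TAZ targets 0.24 (0.0289, 0.258) and unfolded protein response 0.19 (0.000859, 0.258). With an estimated correlation cholesterol synthesis alone stayed past the threshold. With 1 array left out the genes numbered 60 to 347 (347 without resistant tumour 2, 120 and 121 without sensitive tumours 1 and 2, 78 and 60 without parental spheres 1 and 2, 129 and 70 without resistant spheres 1 and 2). Without at least 1 array the call was lost for GALNT5, SLC7A11, CCN1, VCAM1, FXYD3, HPX, ACSS2, MEST, INSIG1, CPT1A, AGXT, MVK, DHCR7 and EBP, at an adjusted p of up to 0.135. So it was for macrophage (up to 0.107), glycolysis (0.107), acute phase (0.131), interferon (0.130), YAP (0.0935), fatty acid oxidation (0.0800) and oxidative phosphorylation lists (up to 0.234, mean -0.089 without resistant tumour 1 or sensitive tumour 1 and -0.21 without sensitive tumour 2), and the ribosome biogenesis mean was 0.16 without sensitive tumour 2. The controls differ between the contrasts, and the spheres' medium and any batch of arrays cannot be told apart from the kind of sample.

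Lower cell cycle and MAPK output after brivanib was weighed against host cells and scaling. Fibroblast (0.21, and 0.080 without brivanib replicate 3) and erythroid (0.19, and 0.15 without brivanib replicate 3, not called) markers were higher. Host cells among the tumour cells would by themselves lower hepatocyte genes, and the plasma protein list was higher by 0.31 ± 0.05 (SE). A rise of these genes within the tumour cells could mask such a fall, so host cells stay open. Quantile normalization left the mean of the 53 cell cycle and MAPK output genes at -0.38 ± 0.13, against -0.43 ± 0.11 as deposited, so scaling is argued against as the whole cause. Less signalling through FGF and VEGF receptors is a candidate explanation that stays open, as a hypothesis, with the design giving no direct measure of it. Any end of sorafenib at the switch stays open too, since the design cannot tell it apart from the start of brivanib.

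NRF2 targets differed between tumours of one group, with AKR1B10 between 5.25 and 10.66 in resistant tumours. Within groups AKR1B10 followed the 17 NRF2 targets outside its family (r = 0.942, permutation p = 0.00579, 10 tumours; 0.877 without the 2 farthest arrays), which argues against an effect of that family's probe sets. The plasma protein list spanned 0.12 over the resistant tumours and the NRF2 list 1.12, which argues against host cells in differing amounts there. Over the sensitive tumours the spans were 0.30 and 0.74 and over the brivanib tumours 0.13 and 0.35, so host cells stay open in those groups. Why these tumours differ was not tested, and no group of the design names a biological cause.

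Lower plasma protein genes in resistant than in sensitive tumours were weighed the same way. Fibroblast and matrix genes were lower as well, by -0.27 ± 0.07 (SE), where more of such host cells in resistant tumours would raise them. With a mouse host and arrays of human sequence, a fall of these genes within the tumour cells would look the same. This value therefore does not decide on host cells. After quantile normalization the list's mean was -0.41 ± 0.10 and as deposited -0.38 ± 0.10, which argues against scaling. The 7 other lists of other cell types ran from -0.22 to 0.015, 0 of them called by camera (adjusted p from 0.0860 to 0.976), so no such list was called higher, and such cells remain open.

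Other splits of the same arrays were counted for each comparison. Chance cannot be excluded for the 2 genes and 10 lists called between resistant and sensitive tumours, since 2 of 35 splits gave as many genes (highest other 175) and 12 as many lists (highest other 16). The split with 175 genes put resistant replicate 2 with the sensitive tumours. It keeps the other 6 arrays in place, and 196 genes were called between the real groups without that array. Nor can it be excluded for brivanib against resistant tumours, where 2 of 35 splits gave as many genes (933, highest other 969, with resistant replicate 1 among the brivanib tumours) and 2 as many lists (16 and 16). The split with 969 genes keeps the other 6 arrays apart as the real one does. More genes were called between the real groups without resistant replicate 1. For spheres against resistant tumours chance can be excluded for the genes (4047, highest other 2144, 1 of 35) but not for the lists (14, highest other 16, 4 of 35). For the difference between the contrasts, over 100 of 700 splits, the real split gave the most genes (218, highest other 149, 1 split). These splits relabel tumours and spheres at once, so they stand for no effect in either contrast and not for equal contrasts. Chance is therefore not excluded for an interaction of genes, nor for the lists (18, highest other 22, 5 splits). With 3 arrays against 3, 10 splits are too few for a share below 0.05. Brivanib against sensitive tumours gave 0 genes by limma (highest other 0, 10 splits as many, 3008 genes at an unadjusted p below 0.05) and 12 lists (highest other 16, 2 splits), and the spheres gave 1134 genes (highest other 0, 1 split) and 19 lists (highest other 10, 1 split).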

How the results depend on the processing

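The least correlated arrays, and each array in turn for the difference between the contrasts, were left out only after the results were seen. No named gene or list reversed its direction in the comparison it was tested in. The sphere value of FREM1 and the tumour values of MVK, TXNIP and MEST changed sign without 1 array. Of 264 gene results 255 kept their side of the threshold after quantile normalization and 239 with trend and robust eBayes, of 235 after centring 229, with probe set means 235 and with array weights 193, and of 242 without dim genes 227. Of 183 with all 16 arrays in one fit 102 did (35 weaker, 46 stronger), of 168 with only the 2 groups 108 (40 weaker, 20 stronger), of 67 with the replicate block 48, of 116 without the less correlated tumours 89, and of 67 without the least correlated sphere 64. Of 1927 with 1 array left out 1558 did, with 360 weaker and 9 stronger, and of 700 list results 603, with 97 weaker. Of 89 list calls 35 were kept by fry and 1 with an estimated correlation. Counts below are of all genes or lists called, with those also called at first in brackets.

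For resistant against sensitive tumours the 2 genes compare with 13 (2) after quantile normalization, 17 (2) after centring, 77 (2) with trend and robust eBayes, 73 (2) without the 40% dimmest genes, 12 (2) with probe set means, 513 (1) with all 16 arrays in one fit, 6 (2) with only the 2 groups compared, 218 (2) with array weights, 0 at 2-fold or more (limma, 2579 at an unadjusted p below 0.05) and 0 without the less correlated arrays. Leaving out 1 array gave 0 to 196 (1 without resistant replicate 1, 196 without 2, 0 without 3 or 4, 0 without sensitive replicate 1 or 2, 9 without 3). The 10 lists compare with 0 with an estimated correlation, 2 (2) with fry and 7 to 17 (7 to 10) with 1 array left out, 17 without resistant replicate 3. For brivanib against resistant tumours the 933 genes compare with 2680 (927) with all 16 arrays, 45 (44) with only the 2 groups, 117 at 2-fold, 234 (219) without the less correlated arrays, and 56 to 1862 with 1 array left out, which was 1862 (903), 242 (225) and 277 (270) for resistant replicates 1, 3 and 4 and 56 (54), 230 (214) and 327 (274) for brivanib replicates 1, 2 and 3. The 16 lists compare with 0 with an estimated correlation, 10 (7) with fry and 11 to 17 (11 to 16) with 1 array left out. For brivanib against sensitive tumours the 0 genes (3008 at an unadjusted p below 0.05) compare with 12 with trend and robust, 11 without dim genes, 672 with all 16 arrays, 500 with only the 2 groups, 1297 with array weights, and 0 with each array left out. The 12 lists compare with 0 with an estimated correlation, 0 with fry, 7 (7) without dim genes and 8 to 13 (5 to 11) with 1 array left out.

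For the spheres the 1134 genes compare with 235 (230) with all 16 arrays, 2106 (1132) with array weights, 90 at 2-fold, 432 (321) with the replicate block, though the shared numbers did not pair arrays (residual r -0.0992 and -0.0925), and 199 to 1203 with 1 array left out, which was 241 (239) and 293 (281) without parental replicates 1 and 2 and 199 (195) and 634 (554) without resistant replicates 2 and 3. The 19 lists compare with 0 with an estimated correlation, 10 (7) with fry and 14 to 19 (14 to 18) with 1 array left out. For spheres against resistant tumours the 4047 genes compare with 511 at 2-fold and 2610 to 4171 with 1 array left out, 2610 (2584) without resistant sphere replicate 2, and the 14 lists with 0 with an estimated correlation and 19 (12) with fry. For the difference between the contrasts the 18 lists compare with 1 with an estimated correlation, 7 (7) with fry and 14 to 21 (14 to 18) with 1 array left out, and the 218 genes with 228 (211) after quantile normalization and 60 to 347 with 1 array left out, which was 347 (208) for resistant tumour 2, 120 (115) and 121 (106) for sensitive tumours 1 and 2, 78 (78) and 60 (60) for parental spheres 1 and 2, and 129 (111) and 70 (70) for resistant spheres 1 and 2. The correlation of the contrasts ran from 0.0603 to 0.194 with 1 array left out. A 2-fold minimum lowers counts by construction, and otherwise the cause was not tested.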

Other observations

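The tests of small RNA genes and of aryl hydrocarbon receptor targets were chosen only after the results were seen. Small nucleolar RNA genes of the C/D class averaged 0.23 ± 0.08 (SE) higher in resistant than in sensitive tumours, 80 of 115 of them in that direction, and those of the H/ACA class 0.16 ± 0.11, 48 of 61. The exact permutation p was 0.0571 and 0.229, and camera gave 6.06e-09 and 1.30e-06 at a preset and 0.0768 and 0.210 with an estimated correlation, without adjustment for the several gene families looked at. By limma 0 single members passed. Brivanib tumours were higher than sensitive ones by 0.19 and 0.28. A shift of all small RNAs on the array could raise them, and 189 microRNA precursor genes, averaging -0.020 ± 0.013, did not show it. The signal level of those genes was not examined, and probe sets near background would not show a shift. The explanation therefore stays open.

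CYP1A1, among the largest rises with brivanib, is a target of the aryl hydrocarbon receptor, and activity of that receptor is a possible explanation. The 6 other measured targets averaged 0.21 ± 0.09 (SE), with camera p = 0.244 at a preset and 0.272 with an estimated correlation. Of these 2 passed the threshold, ALDH3A1 higher by 0.43 (limma adjusted p = 0.0411) and NFE2L2 lower (-0.60, adjusted p = 0.0170). The explanation is neither borne out nor excluded, since the bound that would exclude it was also set after the values were seen and few targets are measured.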
